A study of Mus musculus with 14 samples.

How the data were processed

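The data were messenger RNA profiles of cells sorted by flow cytometry from livers of adult C57BL/6 mice, measured in 14 libraries. Per the labels' protocols, the animals received 0.1% DDC, a porphyrinogenic liver toxicant, over 5 to 8 weeks, livers were digested with collagenase, and 75 to 200 ng of total RNA per sample was prepared with the Illumina TruSeq RNA kit, version 2. The kit selects polyadenylated RNA and does not mark the strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. Whether the libraries with different numbers come from different mice is not stated in the labels, so every p-value measures only the spread between these samples, which may in part be technical.

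The authors deposited a single table of RPKM values (reads normalized to the length of the transcript and to the size of the library), rounded to 2 decimals, with 26005 transcript rows and 1 column per library. Alignment was to mouse genome build mm9, and Bowtie 0.12.7 and CASAVA were used, per the submitters' processing notes. The counting program, the reads taken as the total and the treatment of reads with several matches are not given in the sources used here. Replicates were not pooled in the deposited table. For 12 of the 14 columns the name matched the title of a single sample. The other 2 columns carry the number 220 where the remaining 2 titles carry 120, so these were matched to their group only and are called library 220 here. The series design text gives 3 hepatocyte samples, and 4 were in the table and were used.

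A symbol with more than 1 transcript row (3507 of 20377 symbols) was represented by the row with the highest mean over all libraries, a choice made after the table was seen. Start positions in the table count from 0, since end minus start was a multiple of 3 for 945 of 1125 olfactory receptor rows, whose single coding exons have such lengths, and are given here counted from 1. No 2 libraries shared more than 0.426% identical values, so none was treated as a duplicate. RPKM keeps no read totals. The depth was estimated from the smallest steps between values of transcripts of 150 to 700 nt, with transcript lengths from GENCODE vM21, which is annotated on another build and had a length for 97.6% of the rows. This gave 17900000 to 26800000 reads per library, a 1.50-fold range. With the table's 2 decimals, low values carry rounding and counting error, and no count test was possible.

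Values were tested as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, after keeping the 12638 symbols with at least 1 RPKM in at least 4 libraries. A linear model with the 3 groups was fitted to all 14 libraries, so that the groups share an estimate of the spread, and moderated with a mean-variance trend. Tests were two-sided, adjusted by the Benjamini-Hochberg method over all tested genes of a comparison, and genes with an adjusted p under 0.05 were called. A fold change is on the log2(RPKM + 1) scale, which understates the change of low genes, while a fold given as a ratio compares mean RPKM. Gene lists were fixed from textbook knowledge before the data were examined. There are 34, of which 30 had the 4 tested members needed for a test with camera (limma), which compares a list with all other tested genes at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The same test was repeated with an estimated correlation. For each list and library the mean log2(RPKM + 1) of the measured members is called its score, and scores were compared by an exact permutation test of the difference of means, two-sided, adjusted over the lists. With 5 against 5 or 5 against 4 libraries the smallest p this test can give is 0.00794. Of the list genes, 5 were not found in the table. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the depth estimate, tables and plots.

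The genes named were chosen by a rule fixed before the data were examined. For each comparison it takes the 5 genes higher and the 5 lower with the largest log2 fold change among called genes with a mean of at least 5 RPKM in the higher group and no overlap of library values. Chance gives no overlap for 1.59% of unchanged genes with 5 against 4 libraries and for 0.794% with 5 against 5. It adds 14 fixed marker genes, up to 4 members per list with the smallest adjusted p, and the most abundant member of each list of another cell type. Some genes the rule takes are not reported here. A gene named outside the rule is said to have been chosen after its values were seen.

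The steps were tested on simulated data with 200 genes changed per fold size among the 12638. For hepatocyte-derived ductal cells against hepatocytes, 71.5% of genes changed 1.5-fold, 86% of those changed 2-fold and 96% of those changed 4-fold were called, with 0.224% of unchanged genes. The shares for cholangiocyte-derived ductal cells against hepatocytes were 57.5%, 89%, 97% and 0.174%. For the 2 ductal groups they were 67.5%, 88.5%, 96.5% and 0.266%.

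Titles share numbers between groups. Libraries of the same number deviated together from their group means between the 2 ductal groups (correlations of 0.212 to 0.797 over 3 pairs) and between cholangiocyte-derived ductal cells and hepatocytes (0.133 to 0.512, 3 pairs), so these numbers were taken to pair the samples. Pairs of different numbers reached 0.464 and 0.458. Of the same-number pairs, only number 219 in the former (0.797) and number 118 in the latter (0.512) lay above these values. The number was not part of the model, and the model with it as a block is given where it changes a call. Alternatives covered the pseudocount, the filter, quantile normalization and rescaling by median ratios, the block, fits on only the groups compared, library weights, no trend, a stricter threshold and leaving out each library. Adding transcripts of a symbol, a block from the column numbers, exchanging the labels of scores only within shared numbers, leaving out 3 libraries with transcripts of other cell types and testing lists on rescaled values were chosen after seeing the data. These 3 libraries had the highest macrophage and stellate scores of their groups, and other libraries also held such transcripts.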

Results

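RNA was profiled in 3 cell populations sorted from injured livers of chimeric mice, whose mature hepatocytes carried a red fluorescent marker. Injury was induced with DDC, a porphyrinogenic compound that provokes cholestatic damage and a ductular reaction. Ductal cells were sorted by the ductal surface antigen MIC1-1C3, by low side scatter and by absence of CD11b, CD26, CD31 and CD45, and were divided by the red marker into hepatocyte-derived ductal cells (5 libraries) and cholangiocyte-derived ductal cells (5 libraries). Hepatocytes gave 4 libraries. The labels call the hepatocyte-derived ductal cells donor cells and the cholangiocyte-derived ones host cells. The estimated depth was 17900000 to 26800000 reads per library. Genes at or above 1 RPKM numbered 11857 ± 67.8 in hepatocyte-derived ductal cells, 12342 ± 153 in cholangiocyte-derived ductal cells and 10552 ± 303 in hepatocytes (mean ± SD). The 10 most abundant genes held 14.3 ± 0.413%, 11.9 ± 0.19% and 19.3 ± 1.84% of all RPKM in these groups. Levels below are mean RPKM ± SD over the 5, 5 and 4 libraries, and positions are in mm9.

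Libraries grouped by their population. Across the 12638 tested genes the Spearman correlation of hepatocyte-derived ductal libraries was 0.984 ± 0.0037 with each other, 0.904 ± 0.0083 with cholangiocyte-derived ductal libraries and 0.798 ± 0.021 with hepatocytes. Cholangiocyte-derived ductal libraries and hepatocytes correlated at 0.672. These are correlations across genes, which are not independent replicates. Each of the 5 hepatocyte-derived ductal libraries correlated better with the cholangiocyte-derived ductal group than with hepatocytes, by 0.106 on average and by 0.0656 in library 220, the lowest.

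The first comparison asked how ductal cells that arose from marked hepatocytes differ from hepatocytes of injured livers. Hepatocyte-derived ductal cells held biliary transcripts at high levels and hepatocyte metabolic transcripts at lower levels than hepatocytes. Spp1, the secreted phosphoprotein osteopontin, stood at 17559.8 ± 1096 RPKM against 938 ± 327 in hepatocytes, an 18.7-fold difference, and the biliary transcription factor Sox9 (92.5 ± 15.4 against 7.89 ± 4.12) was 11.7-fold higher. Albumin (Alb) was 7.65-fold lower, at 4654 ± 1407 against 35606 ± 8388, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 52.3-fold lower, at 0.836 ± 0.649 against 43.8 ± 17.9. The hepatocyte regulator Hnf4a remained at 130.3 ± 30.1 against 236 ± 15.1, a log2 fold change of -0.89 ± 0.18 (SE, adjusted p = 3.15e-04), and quantile normalization ended this call (adjusted p = 0.0523).

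Of the 21 biliary markers, 20 rose and none fell in hepatocyte-derived ductal cells. Besides Spp1 and Sox9 these included Bicc1, an RNA-binding protein (NM_031397, chromosome 10, 70387848 to 70622382), with a log2 fold change of 4.49 ± 0.14 (adjusted p = 6.56e-12), Pkhd1, which encodes fibrocystin (3.65), and Itgb4, the hemidesmosome integrin (2.97). Cd24a, a small surface glycoprotein, reached 481 ± 61.6 RPKM from 5.96 ± 7.92, and the adhesion molecule Epcam 85.3 ± 29.5 from 2.88 ± 4.1. The ductal cytokeratins Krt19 and Krt7 rose by 4.11 and 4.35 on the log2 scale, to 42.5 ± 23.4 and 35.7 ± 18.8 RPKM, and Prom1 by 2.29. Library 118 carried the hepatocyte means of Cd24a and Epcam, with ratios of means of 239 and 103 without it in place of 80.7 and 29.7, and Krt19 then rose by 4.88, while without hepatocyte library 611 Prom1 rose by 3.10. The list as a whole was higher than other genes (camera adjusted p = 0.00122, adjusted p = 0.0744 with an estimated correlation). Its score was 5.90 ± 0.18 against 2.42 ± 0.34 (exact permutation test, adjusted p = 0.0112).

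The list called YAP and TEAD targets here also holds Yap1, Wwtr1, Tead1 and Tead4, the factors themselves, so its counts do not measure target genes alone. Of its 14 genes, 13 rose and none fell, led by Ctgf, a matricellular protein (6.22 ± 0.38, 81.3-fold), the phosphatase gene Ptpn14 (4.42 ± 0.14) and the transcription factor Tead4 (2.69 ± 0.11, camera adjusted p = 0.00674 for the list, adjusted p = 0.0899 with an estimated correlation). All 14 genes of the primary cilium list rose, among them the BBSome subunit Bbs2 (2.09) and the ciliary kinesin Kif3a (2.36), and the largest change was in Foxj1 (5.52, 69.1 ± 13.7 against 0.545 ± 0.459 RPKM), a regulator of motile rather than primary cilia (camera adjusted p = 7.39e-04, adjusted p = 0.177 with an estimated correlation). Each of the 11 Notch pathway genes tested rose, with the ligand Jag1 at 75.7 ± 9.86 against 1.41 ± 0.567 RPKM, but the list did not exceed other genes (camera adjusted p = 0.115). After rescaling by median ratios the Notch list was called (0.0108), as were the basement membrane (0.0136) and immediate early lists (0.016), and quantile normalization called these (0.0462, 0.0108 and 6.57e-04) and the junction (0.00464) and chemokine lists (0.0141). With an estimated correlation, run on the deposited scaling only, these lists gave a camera adjusted p of 0.378 to 0.835. As deposited, no call was made for basement membrane and integrin genes (13 of 16 rose, none fell, 0.133), with Itga3 at 4.47 and Itga2 at 4.03, for epithelial junctions and cytokeratins (13 rose and 2 fell of 16, 0.482) and for immediate early and dissociation stress genes (13 of 14 rose, 0.18), with Egr1 at 3.25. Further genes of large change were Rgs5, a regulator of G protein signalling also used as a pericyte marker (120-fold higher, 1399 ± 257 against 11.6 ± 7.26 RPKM), the growth factor Mdk (167-fold) and Igfbp7 (27.4-fold). Without hepatocyte library 118, whose levels of these genes were higher than in the other hepatocytes, the folds of Ctgf, Mdk and Igfbp7 were 242, 358 and 204, and Foxj1 was 218-fold higher in place of 127-fold. Mdk and Foxj1 were near the floor in those other hepatocytes, at 0.27 to 0.54 and 0.27 to 0.37 RPKM.

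All hepatocyte lists were lower than other genes. All 20 secreted plasma proteins fell (camera adjusted p = 6.87e-18), with Fgg, a fibrinogen chain, at -2.65 ± 0.15 and transthyretin (Ttr) at -2.23 ± 0.14. Also lower were all 19 xenobiotic metabolism genes (5.16e-15), such as the bilirubin-conjugating enzyme Ugt1a1 (-3.71) and Fmo5 (-3.14), all 14 genes of bile acid synthesis and hepatocyte transport (2.55e-13), such as Akr1d1 (-4.04), and all 13 of the urea cycle and gluconeogenesis (5.28e-12), such as Ass1 (-4.91) and the pyruvate carboxylase gene Pcx (-3.07). Coagulation and complement genes fell in 17 of 18 cases (5.91e-15), fatty acid oxidation and ketogenesis genes in 12 of 14 (3.66e-12), pericentral genes in 8 of 9 (1.87e-08), tyrosine and phenylalanine catabolism genes in 5 of 6 (2.47e-05) and periportal genes in 7 of 8, with Sdsl higher (6.74e-05). These list calls held with an estimated correlation (adjusted p of 0.0441 to 0.0476). Fah, the last enzyme of tyrosine breakdown, was at 58.9 ± 7.36 against 288 ± 48 RPKM. Of 11 haem synthesis and breakdown genes, 8 fell, and Ppox rose (9.03e-05, adjusted p = 0.175 with an estimated correlation). Among 14 hepatocyte transcription factors 8 fell, led by the nuclear receptors Nr1i3 (-4.29) and Ppara (-2.29), and 3 rose, among them Nr5a2 (1.23). That list was lower than other genes (1.15e-04, adjusted p = 0.0485 with an estimated correlation). The largest decreases by the naming rule were in Cyp3a11, Cyp2c29, the gene 1100001G20Rik, Orm1 and Fabp1 (-6.66, -6.58, -6.13, -6.07 and -6.02). Without hepatocyte-derived library 219, Cyp3a11, Cyp2c29 and Fabp1 were at -5.90, -5.77 and -5.38. Cyp3a11, Cyp2c29, Orm1, Orm2 and Serpina1b have near-identical paralogs, and their values are uncertain where reads could be split between copies.

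Cell cycle genes divided, with 6 of 22 higher, including the helicase subunits Mcm6 (1.72) and Mcm4 (1.64), and 10 lower, and the lower side grew after rescaling (5 and 15) and under quantile normalization (2 and 16). The list was lower than other genes (camera adjusted p = 0.00153, adjusted p = 0.542 with an estimated correlation), a call lost after rescaling by median ratios (0.0935). Its scores, 2.16 ± 0.22 against 2.47 ± 0.37, did not differ beyond the spread (exact permutation test, adjusted p = 0.23). In the list for epithelial-mesenchymal transition 9 of 12 genes rose and 1 fell (camera adjusted p = 0.579), with Vim, an intermediate filament of mesenchymal cells, at 211 ± 33.5 against 17.5 ± 17.1 RPKM (3.94 ± 0.53, adjusted p = 7.16e-06) and Zeb1 at 1.24. Vim was 12.1-fold higher, and 23.2-fold without hepatocyte library 118. Chemokine and inflammation genes rose in 12 and fell in 1 of 18 cases (0.61), and 3 of 4 fetal liver genes rose (0.515), while Afp stood at 3.48 ± 0.676 against 3.48 ± 1.17 RPKM. The fetal liver list shares Cd24a and Tspan8, both tested, with the biliary list, so its counts are not separate from those of the biliary markers. Counts for Wnt targets and progenitor genes (5 higher and 2 lower of 9, 0.534), Hedgehog genes (2 higher and 1 lower of 3), MHC class II and interferon genes (5 higher of 16, 0.534) and mucin and secretory genes (3 higher and 2 lower of 6, 0.274) depended on the scaling, as given with the totals.

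Few markers of other cells were called between these groups, in which hepatocyte library 118 and hepatocyte-derived library 219 stood apart. Macrophage scores were 5.91 in the former and 1.46 to 1.80 in the other hepatocytes, and 0.994 in the latter and 3.01 to 3.42 in the other hepatocyte-derived ductal libraries. Endothelial scores were likewise 3.44 and 0.46 to 0.953, and 0.499 and 1.55 to 1.93. The stellate score passed without hepatocyte library 118 (a difference of 1.06, exact permutation p = 0.0179). Among stellate and fibroblast markers Rgs5 alone of 11 was called (camera adjusted p = 0.117). Of 14 endothelial markers, Egfl7 was the single call, and of 13 macrophage markers Csf1r rose and Cd68 fell. Camera placed both lists below other genes (0.0358 and 0.0303, with adjusted p = 0.699 for each with an estimated correlation). The endothelial call was lost without hepatocyte-derived library 219 (0.0908), cholangiocyte-derived libraries 118 (0.073) or 220 (0.0776) or hepatocyte library 118 (0.459) and with a pseudocount of 0.1 (0.0526), and the macrophage call without hepatocyte-derived library 219 (0.0899) or hepatocyte library 118 (0.341). Neither was called after rescaling (0.787 and 0.667), under quantile normalization (0.138 and 0.539) or without the 3 libraries with transcripts of other cells, which are cholangiocyte-derived libraries 118 and 220 and hepatocyte library 118 (0.596 and 0.341). Nor was either called with the sample number as a block, as given in the last part on processing. Leaving out the 3 libraries did not leave the rest free of macrophage transcripts. Macrophage scores were 3.01 to 3.42 in hepatocyte-derived libraries other than 219, and 3.79 and 3.86 in cholangiocyte-derived libraries 225 and 611. Clec4g, S100a9 and Cd14 were not called (11.7 ± 6.89 against 28.8 ± 52.2, 16.3 ± 11.3 against 10.4 ± 17.2 and 94.1 ± 21.6 against 85.3 ± 7.94 RPKM), and Cd14 became lower after rescaling. Library 118 carried the hepatocyte mean of Clec4g (106.9 against 0.84 to 5.71 RPKM in the others). Without it the log2 fold changes of Clec4g and S100a9 were 1.60 and 2.44 (adjusted p = 0.136 and 0.0723), and with library weights both were called higher in hepatocyte-derived ductal cells, at log2 fold changes of 2.34 (adjusted p = 0.00677, 0.00677 to 0.973 over the alternatives) and 3.18 (0.0023, 1.45e-04 to 0.629). Both were also called higher with the sample number as a block. The platelet gene Pf4 was called at 2.43 ± 1.5 against 0.985 ± 1.92 RPKM (adjusted p = 0.0277), as were both other platelet genes tested. Hepatocyte library 118 carried the hepatocyte mean of Pf4 (3.87 against 0 to 0.07 RPKM in the others), and the Pf4 call was lost without hepatocyte-derived library 611 (0.0732) or hepatocyte library 225 (0.0822), 248 (0.0887) or 611 (0.0889), after rescaling (0.14), under quantile normalization (0.479), with a pseudocount of 5 (0.11) and in a fit on only these 2 groups (0.0594). Both erythroid genes tested fell, among them Alas2 (-3.36). None of 4 neutrophil genes (0.54) and none of 4 sex-linked genes (0.351) was called, and no lymphocyte gene passed the filter.

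In total, limma called 8363 genes higher and 1873 lower in hepatocyte-derived ductal cells than in hepatocytes, of which 4302 and 941 changed at least 2-fold. The median log2 fold change of all tested genes was 0.67, so the direction of small changes depends on the scaling. After rescaling by median ratios the median was 0.04 and the calls divided into 4842 higher and 4486 lower, and after quantile normalization into 4596 and 4136. Under rescaling, called members of the lists for Wnt targets became mostly lower (3 higher and 4 lower), as did MHC class II and interferon genes (1 and 3, and 3 and 4 under quantile normalization), and Hedgehog genes divided evenly, and of macrophage markers 1 rose and 2 fell, while quantile normalization turned the mucin (1 and 2), endothelial (0 and 5), stellate (1 and 2) and platelet (0 and 1) counts. The biliary, YAP, cilium, Notch, junction and hepatocyte lists kept their direction. Without the 3 libraries with transcripts of other cells the counts were 8495 and 1830. Camera placed 3 lists higher and 14 lower, and 10 of these 17 calls held with an estimated correlation. Adjusted over the list alone, counts were as given except that a fatty acid oxidation gene was added as higher and the endothelial call was lost. List medians and camera directions differed in sign for Wnt targets (median 0.91, camera lower), MHC class II (0.72), mucin (0.43, with a mean of -0.03), endothelial (0.07), macrophage (0.12), neutrophil (1.05) and sex-linked genes (0.52), and the stellate list had a median of -0.08 with a mean of 0.63.

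**Figure D1:**
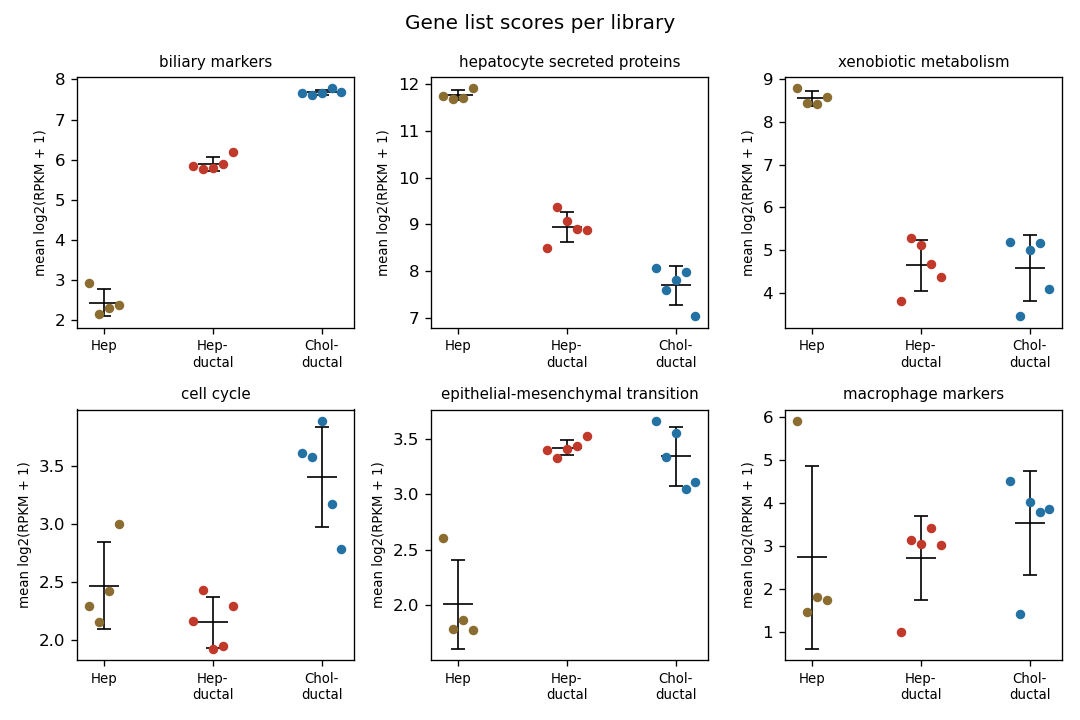
Scores of 6 gene lists, the mean log2(RPKM + 1) of the members of each list, in the libraries of hepatocytes (Hep, n = 4), hepatocyte-derived ductal cells (Hep-ductal, n = 5) and cholangiocyte-derived ductal cells (Chol-ductal, n = 5). Points are libraries, and bars are means ± SD. Biliary scores lie at 2.42, 5.90 and 7.68 in these groups, secreted protein scores at 11.8, 8.95 and 7.70, and the highest macrophage score, 5.91, belongs to a hepatocyte library.

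The second comparison, cholangiocyte-derived ductal cells against hepatocytes, gives the distance between the resident ductal lineage and hepatocytes. The labels call the cholangiocyte-derived cells host cells, while mature hepatocytes carried the marker of the donor ductal cells. Host and donor may therefore differ here too, and in the shares of the way given below. Cholangiocyte-derived ductal cells held Krt19 at 658 ± 65.2 against 2.86 ± 5.01 RPKM, a 230-fold difference, Krt7 at 302 ± 71.5 against 1.11 ± 2.02 (271-fold), Epcam at 546 ± 52 against 2.88 ± 4.1 (190-fold) and Cd24a at 676 ± 85.6 against 5.96 ± 7.92 (113-fold). Library 118 carried the hepatocyte means of these 4 genes, and without it the folds were 1845, 2921, 660 and 335. The folds without it rest on hepatocyte values near the floor, such as 0.09 to 0.67 RPKM for Krt19 and 0.03 to 0.18 for Krt7, and are imprecise. Matrilysin (Mmp7), a protease of injured epithelia, had the largest log2 fold change by the naming rule (8.19 ± 0.73), from 4.91 ± 8.96 to 814 ± 286 RPKM. Without hepatocyte library 118 it was 9.15, and the ratio of the means went from 166 to 1864, with Mmp7 at 0 to 1.11 RPKM in the other hepatocyte libraries. The plasma protein, urea cycle, bile acid and drug metabolism genes tested were called lower, except 1 of drug metabolism. Alb was 12.4-fold lower at 2873 ± 489 RPKM, and Hnf4a 4.05-fold lower at 58.3 ± 10.8.

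Of 21 biliary markers 20 rose and none fell (camera adjusted p = 2.01e-04, adjusted p = 0.0426 with an estimated correlation). The smallest adjusted p among them belonged to Itgb4 (NM_133663, chromosome 11, 115836039 to 115869725), with a log2 fold change of 5.40 ± 0.12 (adjusted p = 2.66e-13), and Cldn4, a tight junction claudin (5.05 ± 0.16), and Pkhd1 (4.24) were among the next. Krt19 (NM_008471, chromosome 11, 100002126 to 100007233) changed by 8.17 ± 0.55, and Spp1, Sox9 and Prom1 by 4.38, 3.60 and 4.68. Krt19 changed by 8.94 without hepatocyte library 118 and Prom1 by 5.49 without hepatocyte library 611. All 11 Notch genes rose, with Jag1 at 5.01 and the ligand Dll1 at 2.11 (camera adjusted p = 0.0392, adjusted p = 0.261 with an estimated correlation). That call was lost without hepatocyte library 118 (0.067) and without the 3 libraries with transcripts of other cells (0.0621). All 14 genes of the YAP and TEAD list rose (0.00751, adjusted p = 0.0915 with an estimated correlation), among them Ctgf (7.50), Ptpn14 (4.52), Tead4 (2.48) and the coagulation initiator F3 (4.73), and all 14 cilium genes (0.00147, adjusted p = 0.198 with an estimated correlation), among them Bbs2 (2.94) and Foxj1 (6.07). Basement membrane and integrin genes rose in 14 and fell in 2 of 16 cases (0.0338, adjusted p = 0.174 with an estimated correlation), with Itga3 at 4.44 ± 0.11, and this call too was lost without those 3 libraries (0.101) and with a pseudocount of 0.1 (0.0605).

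All hepatocyte lists were lower than other genes. All 20 secreted proteins fell (camera adjusted p = 1.28e-18), such as Fgg (-3.90 ± 0.15), Fga (-3.69 ± 0.16) and Ttr (-2.81 ± 0.14), and so did all 18 coagulation and complement genes (3.09e-16), such as C9 (-4.23 ± 0.20) and F11 (-3.99 ± 0.20). All 14 bile acid genes (1.38e-12), all 13 urea cycle and gluconeogenesis genes (4.75e-12) and all 6 tyrosine and phenylalanine catabolism genes (9.25e-06) fell, with Cyp7a1 at -4.32 and Fah at -4.30. Xenobiotic metabolism genes fell in 18 of 19 cases (4.16e-13), fatty acid oxidation and ketogenesis genes in 13 of 14 (1.38e-12) and periportal genes in 7 of 8, with 1 higher (1.43e-05). Hepatocyte transcription factors fell in 10 of 14 cases and 3 rose (1.14e-05). These calls held with an estimated correlation (0.0375 to 0.0424). The calls of pericentral genes (7 of 9 fell, 2.30e-06) and of haem synthesis and breakdown (9 of 11 fell and 1 rose, 2.28e-04) did not (adjusted p = 0.063 and 0.198 with an estimated correlation). The largest decreases were in Cyp3a11 (-6.10), Cyp2c29 (-6.08), 1100001G20Rik (-5.85), Orm1 (-5.77) and Orm2 (-5.73). Without cholangiocyte-derived library 219 the first 4 of these were at -5.09, -5.13, -5.04 and -5.05.

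Cell cycle genes rose in 13 of 22 cases and fell in none, led by Mcm4 (2.42), Mcm5 (2.29) and Mcm6 (2.03), with scores of 3.41 ± 0.43 against 2.47 ± 0.37 (exact permutation test, adjusted p = 0.04). With fewer libraries the score no longer passed, without cholangiocyte-derived library 118, 219, 220 or 225 or hepatocyte library 118, 225 or 248 (exact permutation p of 0.0536 to 0.0571), nor did it with labels exchanged only within shared sample numbers (exact permutation p = 0.0833). The list did not exceed other genes (camera adjusted p = 0.872), and its calls became 7 higher and 3 lower after rescaling and 6 higher and 8 lower under quantile normalization. In the epithelial-mesenchymal list 8 genes rose and 3 of 12 fell (0.693), and Vim was at 45.8 ± 25.4 against 17.5 ± 17.1 RPKM (adjusted p = 0.0136), a call lost without hepatocyte library 611 (0.058), after rescaling (0.185) and under quantile normalization (0.0708). The ratio of the Vim means was 2.62, and 5.02 without hepatocyte library 118. Epithelial junctions and cytokeratins rose in 13 and fell in 1 of 16 cases (0.24), with the epithelial splicing factor Esrp1 (4.92) and the transcription factor Grhl2 (4.54) among the leading changes. Chemokine and inflammation genes rose in 14 and fell in 1 of 18 (0.285), with Cx3cl1 at 3.52 and Relb at 2.66. Immediate early and dissociation stress genes rose in 13 of 14 (0.106), and with the sample number as a block this list was called (0.0185), as it was after rescaling (0.00725), when the chemokine list was called too (0.0162). Quantile normalization called the junction (7.60e-04), chemokine (0.00135) and immediate early lists (3.14e-04). With an estimated correlation, run on the deposited scaling only, these lists gave a camera adjusted p of 0.52, 0.785 and 0.785. Of the remaining lists, 10 of 16 MHC class II and interferon genes rose (0.826), with 4 higher and 1 lower after rescaling and 6 and 4 under quantile normalization, 3 of 4 fetal liver genes rose (0.635), Wnt targets divided into 5 higher and 2 lower of 9 (0.533), Hedgehog genes into 2 and 1 of 3, and mucin and secretory genes into 3 and 3 of 6 (0.374), with Muc1 at 7.35.

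Stellate and fibroblast markers rose in 10 of 11 cases, though not beyond other genes (camera adjusted p = 0.826). Col1a1 was at 35.6 ± 40 against 1.93 ± 3.46 RPKM (3.26 ± 0.86, adjusted p = 0.00278) and Rgs5 at 579.6 ± 154 against 11.6 ± 7.26. The ratio of the Col1a1 means was 18.5, and it was 178 without hepatocyte library 118 (log2 fold change 3.95) and 12.2 without cholangiocyte-derived library 220. Col1a1 was near the floor in the other hepatocyte libraries, at 0.01 to 0.32 RPKM. The scores of this list were 4.41 and 4.59 in cholangiocyte-derived libraries 118 and 220 and 2.22 to 2.92 in the other 3, and their cell cycle scores were 3.62 and 3.89 against 2.79 to 3.58. Among macrophage markers Cd14 (346 ± 52.6 against 85.3 ± 7.94 RPKM) and Csf1r (3.22, and 4.15 without hepatocyte library 118) were called of 13 (0.285), of 14 endothelial markers Egfl7 and Vwf (0.299), and 2 of 4 neutrophil markers (0.792), which were the low genes Retnlg and Csf3r. Clec4g and S100a9 were not called (24.4 ± 18.4 and 28.7 ± 30.4 RPKM). With the sample number as a block both were, at log2 fold changes of 1.66 (adjusted p = 0.048) and 2.64 (4.95e-04), as they were with library weights (0.00108 and 8.14e-04) and without hepatocyte library 118 (0.0276 and 0.0309), and S100a9 without cholangiocyte-derived library 219 (0.0398). Pf4 (3.02) was 1 of 2 platelet genes called higher of 3, both erythroid genes fell (Alas2 -3.39), and none of the 4 sex-linked genes was called (0.374).

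Limma called 8475 genes higher and 2195 lower in cholangiocyte-derived ductal cells than in hepatocytes, 5055 and 1225 of them at least 2-fold. The median log2 fold change was 0.76. Rescaling gave 5257 higher and 4688 lower, with a median of 0.09, and quantile normalization 4891 and 4769. Under these scalings the called members of the Wnt (4 and 5 after rescaling), endothelial (0 and 2 under quantile normalization) and platelet lists (1 and 2 under quantile normalization) turned, Hedgehog genes divided evenly and the neutrophil calls were lost, while the biliary, Notch, YAP, cilium, basement membrane, stellate and hepatocyte lists kept their direction. Without the 3 libraries with transcripts of other cells, 8248 and 2015 genes were called. Camera placed 5 lists higher and 11 lower, and 10 of the 16 held with an estimated correlation. Adjusted over the list alone, 9 MHC class II and interferon genes, 1 endothelial gene and no neutrophil gene were called higher, and the other counts were as given. Medians were above 0 while camera pointed lower for Wnt targets (0.39), the epithelial-mesenchymal list (1.52), MHC class II (0.95), mucin (0.81), endothelial (0.66), macrophage (0.92), neutrophil (1.64) and sex-linked genes (0.45).

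**Figure D2:**
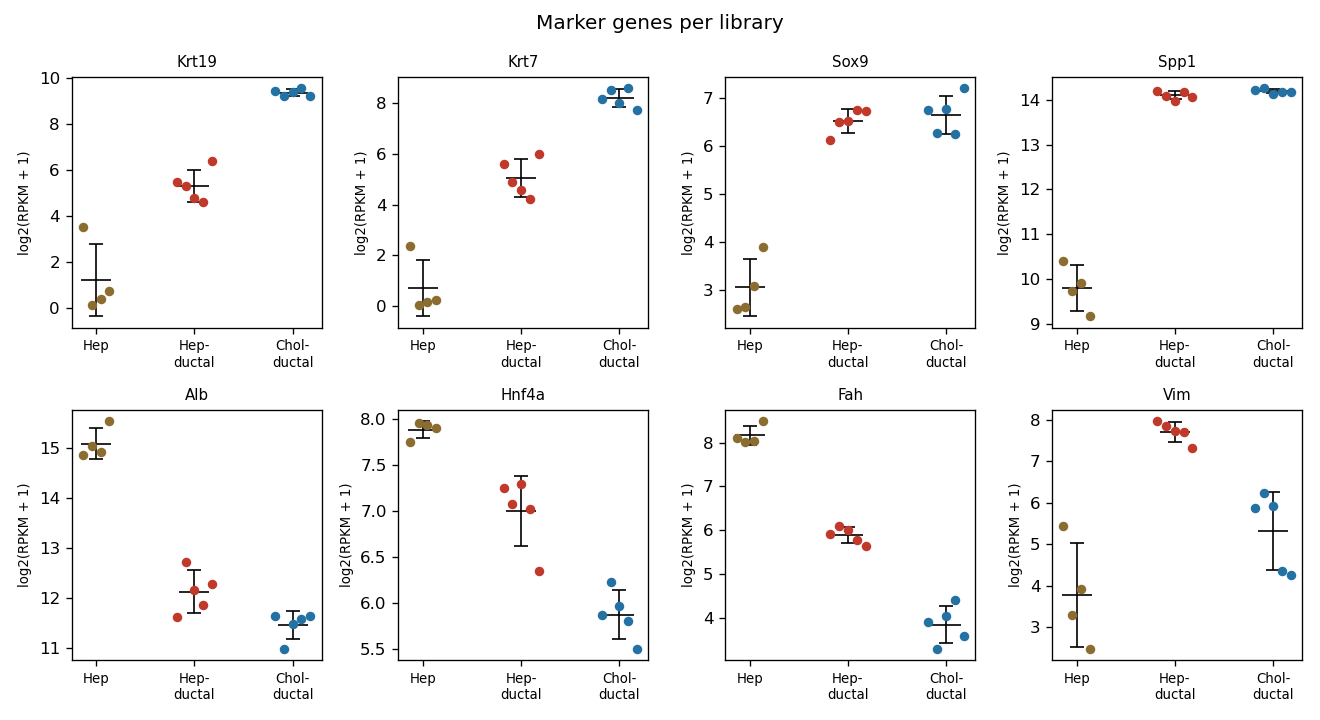
Expression of 8 marker genes as log2(RPKM + 1) in each library of hepatocytes (Hep, n = 4), hepatocyte-derived ductal cells (Hep-ductal, n = 5) and cholangiocyte-derived ductal cells (Chol-ductal, n = 5). Points are libraries, and bars are means ± SD. Spp1 lies at 17559.8 and 18618 RPKM in the 2 ductal groups, Krt19 lies at 42.5 and 658 RPKM in them, and Vim is highest in hepatocyte-derived ductal cells, at 211 RPKM.

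Both ductal groups were compared with the same hepatocyte libraries. In both comparisons 7806 genes were higher and 1707 lower, and 87 went in opposite directions. These counts are on the deposited scaling. Rescaling by median ratios left 4842 and 5257 genes higher and 4486 and 4688 lower, so at most 4842 could then be shared as higher. Independent lists of the deposited scaling would share 5608 and 325. Simulated groups without any change, with hepatocytes simulated too, shared 0. Hardly any gene can be called in such data, so this count does not show how shared hepatocyte libraries affect called genes. With the hepatocyte libraries split between the comparisons, 7136 (range 7022 to 7288) and 1531 (1474 to 1595) were shared. The correlation of log2 fold changes was 0.893, against 0.563 for simulated unchanged groups, and the covariance was 1.80 against 0.0242 simulated and 1.75 with split hepatocytes. On the log2 scale, the members of a list called and at least 2-fold changed in cholangiocyte-derived ductal cells had, in hepatocyte-derived ductal cells, covered a median of 67.6% of the way from hepatocytes for biliary markers and 68% for secreted proteins, 93.2% for xenobiotic metabolism and 94.9% for bile acid genes. Members of these lists ranged from 17.8 to 99.8%, 25.4 to 105%, 32.8 to 118% and 41.3 to 108%. Differences between lists were not tested, and members were chosen by their change in cholangiocyte-derived ductal cells, which enters the share. The share was 88.5% for cilium genes, 86.9% for YAP and TEAD targets, 78.9% for the urea cycle and gluconeogenesis, 64.4% for Notch genes, 54.5% for basement membrane and integrins, 47.5% for the cell cycle and -6.8% for stellate and fibroblast markers. The cell cycle share rests on 10 members and ranged from -94.7 to 84.7%. Of all 22 tested cell cycle members, 6 were higher and 10 lower in hepatocyte-derived ductal cells than in hepatocytes, so this share does not describe the list. The stellate share ranged from -23.6 to 123% over members. It is measured from hepatocytes that include library 118, whose stellate score was 2.84 (0.651 to 0.858 in the others). Without that library the stellate score of hepatocyte-derived ductal cells was 1.06 above that of hepatocytes, so the sign of this share is uncertain.

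The third comparison asked how ductal cells sorted by the same surface markers differ by origin. Origin coincides with donor and host in the labels, so differences by origin cannot be told apart from differences between donor and host animals. Hepatocyte-derived ductal cells had lower levels of biliary markers and higher levels of secreted plasma proteins than cholangiocyte-derived ductal cells, though neither list was called with an estimated correlation (adjusted p = 0.122 and 0.31). Muc1, a membrane mucin of ductal epithelia, was at 4.63 ± 2.17 against 258 ± 38.6 RPKM, 55.7-fold lower, and Krt19 and Epcam were 15.5-fold and 6.39-fold lower. Spp1 (17559.8 ± 1096 against 18618 ± 588) and Sox9 (92.5 ± 15.4 against 103 ± 29.1) did not differ beyond the spread (adjusted p = 0.781 and 0.743). The plasma glycoprotein Ahsg was 5.94-fold higher at 3742 ± 601 against 629.8 ± 271 RPKM, and Hnf4a 2.23-fold higher. Vim was 4.62-fold higher, at 211 ± 33.5 against 45.8 ± 25.4.

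Of 21 biliary markers 14 fell and none rose (camera adjusted p = 6.43e-06, adjusted p = 0.122 with an estimated correlation), with scores of 5.90 ± 0.18 and 7.68 ± 0.06 (exact permutation test, adjusted p = 0.0208). Muc1 (NM_013605, chromosome 3, 89032974 to 89037291) had a log2 fold change of -5.62 ± 0.36 (adjusted p = 2.59e-08), Cldn4 -3.15 ± 0.15 and Itgb4 -2.43 ± 0.11. Krt19, Krt7 and Prom1 fell by 4.06, 3.16 and 2.39 on the log2 scale, and Cd24a stood at 481 ± 61.6 against 676 ± 85.6 RPKM (adjusted p = 0.403). Cd24a was called lower without hepatocyte library 118 (0.0101), without the 3 libraries with transcripts of other cells (0.0335), in a fit on only the ductal groups (0.00458) and with library weights (0.0319). Other large decreases were in Mmp7 (70.4-fold), the epithelial small GTPase Rab25 (53.7-fold), mesothelin (Msln, 49.1-fold) and the GABA receptor subunit Gabrp (33.5-fold). Basement membrane and integrin genes fell in 11 and rose in 2 of 16 cases (0.00231, adjusted p = 0.239 with an estimated correlation), with the epithelial integrin Itgb6 at 0.934 ± 0.532 against 32.5 ± 9.43 RPKM and the laminin chains Lama3 (-2.65) and Lamb3 (-4.17) also lower. Among epithelial junctions and cytokeratins 6 of 16 fell and 2 rose (0.103, and 0.0107 under quantile normalization). Esrp1 was at 0.634 ± 0.498 against 31.8 ± 1.84 RPKM, with 0.090 ± 0.154 in hepatocytes, and Grhl2 at 1.0 ± 0.909 against 24.7 ± 2.84, 24.7-fold lower and 40.8-fold without hepatocyte-derived library 611.

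Of the hepatocyte lists, 8 were higher than other genes in hepatocyte-derived ductal cells, though none with an estimated correlation, and the xenobiotic, haem and pericentral lists were not called. Secreted proteins rose in 16 of 20 cases and fell in none (camera adjusted p = 1.19e-08, adjusted p = 0.31 with an estimated correlation), led by Itih4 (2.13 ± 0.18), Ahsg (2.65 ± 0.25), Fgb (2.33) and Fga (1.45). Alb was 1.62-fold higher (adjusted p = 0.0359), a call lost without hepatocyte-derived library 220 (0.0899), 225 (0.0706) or 611 (0.0728) and without cholangiocyte-derived library 219 (0.0924), 220 (0.0646) or 225 (0.0541), without the 3 libraries with transcripts of other cells (0.0613), under quantile normalization (0.838), with a pseudocount of 0.1 (0.0607) and with no filter (0.556). Coagulation and complement genes rose in 13 of 18 cases (5.08e-07, adjusted p = 0.31 with an estimated correlation), with coagulation factor F9 at 2.68 ± 0.26 and complement factor Cfb at 1.01 ± 0.11. Hepatocyte transcription factors rose in 7 of 14 (0.0123, adjusted p = 0.31 with an estimated correlation), with Creb3l3 at 2.59 ± 0.25, Foxa3 at 1.30 ± 0.16 and Hnf4a at 1.13 ± 0.17. Also higher were 9 of 14 fatty acid oxidation genes (3.72e-04), 7 of 13 urea cycle and gluconeogenesis genes (7.84e-04), 4 of 8 periportal genes (0.0158), 2 of 6 tyrosine and phenylalanine catabolism genes (0.0346), with Fah at 2.04 ± 0.18, and 6 of 14 bile acid genes (0.0405). With an estimated correlation these gave adjusted p = 0.31, 0.359, 0.31, 0.359 and 0.487. The tyrosine call was lost without hepatocyte-derived library 220 (0.0583) or cholangiocyte-derived library 219 (0.0697), and under quantile normalization (0.0626), and the bile acid call under both scalings (0.0529 rescaled, 0.0626 quantile) and without hepatocyte-derived library 220 (0.0713) or 225 (0.0557) or cholangiocyte-derived library 219 (0.112). Xenobiotic genes divided into 2 higher and 1 lower of 19 (0.2) and were called higher as a list without the 3 libraries with transcripts of other cells (0.0387). Cyp7a1 was near 1 RPKM in both groups (0.836 ± 0.649 and 1.34 ± 1.2).

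All 22 cell cycle genes were lower in hepatocyte-derived ductal cells (camera adjusted p = 3.84e-07, adjusted p = 0.359 with an estimated correlation), among them the cyclin Ccnb2 (2.09 ± 1.08 against 11.4 ± 4.54 RPKM, -1.99 ± 0.27) and Pcna (25.7 ± 2.31 against 45.3 ± 4.33, -0.80 ± 0.10). The scores were 2.16 ± 0.22 and 3.41 ± 0.43 (exact permutation test, adjusted p = 0.0208). Stellate and fibroblast markers moved with this list, with 8 of 11 lower, 1 higher and scores of 1.82 ± 0.26 and 3.40 ± 1.04 (camera adjusted p = 0.0544, 0.00588 with the sample number as a block). Lum was at 1.06 ± 0.757 against 19.4 ± 16.5 RPKM, and Rgs5 was the member that was higher (1399 ± 257 against 579.6 ± 154). Macrophage scores were 2.72 ± 0.98 and 3.53 ± 1.21 (exact permutation test, adjusted p = 0.405). With labels exchanged only within shared sample numbers, the macrophage score was lower in all 3 shared numbers (differences of -0.85 to -0.43, exact permutation p = 0.0417, adjusted p = 0.0545), where 0.0417 is the smallest p this test can give. The libraries numbered 220 of both ductal groups were left unpaired in it. Pairing them too would leave fewer exchanges and a smallest possible p above 0.05. The unpaired macrophage and endothelial scores passed without cholangiocyte-derived library 219 (-1.33 and -0.932, exact permutation p = 0.0159 for each). Cd14 was the single macrophage marker called of 13 (-1.88 ± 0.15, 0.337 for the list).

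In the epithelial-mesenchymal list 5 of 12 genes were higher and 2 lower (camera adjusted p = 0.0996). Higher were Vim (2.39 ± 0.50), Zeb1 (1.63 ± 0.12), a transcription factor that represses epithelial genes, and the cadherin Cdh2 (2.18), and Itgb6, an epithelial integrin listed there, was lower (-4.11). The list was called with the sample number as a block (0.0323), without hepatocyte library 118 (0.0468) and without the 3 libraries with transcripts of other cells (0.00347). Chemokine and inflammation genes fell in 8 and rose in 1 of 18 cases (0.0419, adjusted p = 0.598 with an estimated correlation), with Cxcl5 at 19.1 ± 10 against 269.5 ± 100.1 and Cx3cl1 at 12.4 ± 3.75 against 44.7 ± 5.55 RPKM. This call was lost with the block (0.0595) and without hepatocyte-derived library 219 (0.089), 220 (0.0583) or 225 (0.0554) or cholangiocyte-derived library 118 (0.0682) or 611 (0.0652). Notch genes fell in 5 of 11 cases (0.062), with Dll1 at -1.72, and cilium genes in 7 of 14 (0.0544), with Bbs2 at -0.85. Both lists were called with the block (0.025 and 0.0401), Notch also without cholangiocyte-derived library 219 (0.0439) or 225 (0.0264), and cilium without hepatocyte-derived library 219 (0.0463), cholangiocyte-derived library 118 (0.0232) or 225 (0.0462) or the 3 libraries (0.0216), after rescaling (0.0437), under quantile normalization (0.038) and with a pseudocount of 0.1 (0.0442). The stellate list was also called without cholangiocyte-derived library 219 (0.0439) or 225 (0.0119), under quantile normalization (0.0339) and with a pseudocount of 0.1 (0.0344). YAP and TEAD targets fell in 5 of 14 (0.249), with Amotl1 at -2.88. Immediate early genes fell in 3 of 14 (0.134, and 0.0465 and 0.0413 without cholangiocyte-derived libraries 219 and 225 and 0.0276 under quantile normalization), with Nr4a1 at -2.32. By score, which compares the groups and not a list with other genes, the YAP (5.14 against 5.80), Notch (2.75 against 3.35), cilium (3.85 against 4.11), junction (6.02 against 6.60), basement membrane (4.19 against 5.44), stellate and mucin lists (1.38 against 2.10) were lower in hepatocyte-derived ductal cells with no overlap of libraries (exact permutation test, adjusted p = 0.0208 for each). With the median of members the YAP and junction scores no longer passed (exact permutation p = 0.19 and 0.0952). The bile acid score did not pass (exact permutation test, adjusted p = 0.0736), though it was higher in all 3 shared sample numbers (differences of 0.48 to 0.70). With labels exchanged only within shared numbers no score between the ductal groups passed after adjustment. The scores of these 7 lists and of the biliary, cell cycle and bile acid lists were then at the smallest p this test can give (exact permutation p = 0.0417, adjusted p = 0.0545). With the ductal libraries numbered 220 paired as well, no score could reach 0.05 even before adjustment. MHC class II and interferon genes fell in 3 of 16 (0.758), with Cd74 at -2.10.

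Wnt targets had 1 higher and 1 lower of 9 (camera adjusted p = 0.489), Hedgehog genes 1 lower of 3, fetal liver genes 1 lower of 4 (0.765), haem genes 2 higher and 2 lower of 11 (0.758), pericentral genes 1 higher and 3 lower of 9 (0.671), mucin and secretory genes 2 higher and 3 lower of 6 (0.507) and platelet genes 1 higher and 1 lower of 3, with Pf4 lower (-1.93). The mucin list held Spdef (1.22) above and Tff2 (-3.09) below its level in cholangiocyte-derived ductal cells. None of 14 endothelial (0.438), 4 neutrophil (0.815), 2 erythroid and 4 sex-linked genes (0.77) was called, with Clec4g, S100a9 and Alas2 at adjusted p = 0.593, 0.762 and 0.946. The highest genes by the naming rule were Ms4a4d (82.9 ± 25.8 against 4.54 ± 4.79 RPKM), the recombination gene Rad51l1 (79.5 ± 22.2 against 6.72 ± 8.54), Rgs4, a relative of Rgs5 (27.2 ± 17.8 against 1.3 ± 0.58), the transporter Slc6a13 (87.7 ± 16.9 against 8.72 ± 4.32) and the serpin Serpina1b (1452 ± 281 against 175 ± 112). Cholangiocyte-derived library 219 carried the lower means of Ms4a4d and Rad51l1, whose ratios were 18.3 and 11.8 with it and 32.5 and 27.2 without it. Slc6a13 and Serpina1b were at 144 ± 14.8 and 1687 ± 248 in hepatocytes, whereas Ms4a4d and Rgs4 were at 0.797 ± 1.21 and 0.217 ± 0.162.

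Limma called 1913 genes higher and 2657 lower in hepatocyte-derived than in cholangiocyte-derived ductal cells, 517 and 979 of them at least 2-fold, with a median log2 fold change of -0.03. Rescaling gave 2112 and 2434, and quantile normalization 3069 higher and 2403 lower, so that the larger side changed. The lists described kept their direction under both scalings, except that Hedgehog lost its call under quantile normalization, where fetal liver genes divided evenly, Wnt targets into 3 higher and 1 lower and haem genes into 2 and 1. Without the 3 libraries with transcripts of other cells, 1811 and 2494 genes were called. Camera placed 8 lists higher and 4 lower, none with an estimated correlation, where all 30 lists gave an adjusted p of 0.122 or more. Adjusted over the list alone, 1 biliary, 1 YAP and 1 cilium gene were also called higher, 17 secreted proteins and 3 tyrosine genes were higher, 7 junction, 9 cilium, 9 stellate and 2 immediate early genes were lower, and other counts were as given. Haem genes had a median of -0.01 with a mean of 0.05 and camera pointing higher, and the Hedgehog and platelet lists had medians of 0.05 and 0.04 with means of -0.18 and -0.47.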

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

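The tests of carried-over hepatocyte transcripts and both tests of hepatocyte library 118 were chosen only after the result was seen. In groups of 4 or 5 libraries, a value was singled out when its gap to the nearest library, relative to the range of the group, exceeded the critical value of Dixon's test. Chance gives about 1 in 20 groups, and here 61 of 330 tested (18.5%) were found, 30 of them in hepatocyte library 118. Levels are in RPKM and scores are list means of log2(RPKM + 1), each with the range of the other libraries of its group.

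Hepatocyte library 118 had the highest sum of RPKM, 797673 against 685824 to 693516. Its scores were higher for markers of macrophages (5.91 against 1.46 to 1.80), endothelial cells (3.44 against 0.46 to 0.953), stellate cells and fibroblasts (2.84 against 0.651 to 0.858), lymphocytes (0.283 against 0.014 to 0.045), erythroid cells (1.55 against 0.686 to 0.83) and platelets (0.615 against 0.179 to 0.229), and for the epithelial-mesenchymal list (2.60 against 1.77 to 1.87). Among genes of other cells it held Clec4g at 106.9 (0.84 to 5.71), S100a9 at 36 (0.09 to 4.95), Col1a1 at 7.12 (0.01 to 0.32), Lum at 13.5 (0.15 to 0.53), Pf4 at 3.87 (0 to 0.07) and Igfbp7 at 130.1 (2.34 to 7.18). Ductal genes were also higher there, with Krt19 at 10.4 (0.09 to 0.67), Krt7 at 4.14 (0.03 to 0.18), Epcam at 9.02 (0.71 to 0.98), Cd24a at 17.8 (1.5 to 2.98), Mmp7 at 18.3 (0 to 1.11), Muc1 at 2.98 (0.05 to 0.33), Msln at 1.86 (0 to 0.07), Rab25 at 1.71 (0 to 0.04), Gabrp at 2.11 (0.01 to 0.14), Itgb4 at 0.48 (0.04 to 0.11), Ctgf at 7.57 (0.71 to 1), Cxcl5 at 7.83 (0.31 to 0.5), Foxj1 at 1.23 (0.27 to 0.37), Mdk at 2.05 (0.27 to 0.54) and Ms4a4d at 2.6 (0.08 to 0.33). Orm1, an acute-phase gene of hepatocytes, was at 2487 (1535 to 1615).

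Other cells or their RNA in the hepatocyte sort are a candidate source of these values in library 118, which stays open. All 7 lists of other cell types tested, biliary markers included, had a higher score there than in each of the other 3 hepatocyte libraries, but these scores are the pattern itself and cannot decide it. The most abundant members were Lyz2 at 589 (2.71 to 10.99), Dcn at 97 (1.27 to 2.4) and Spp1 at 1364 (577.6 to 964.9) of the macrophage, stellate and biliary lists, Gzma at 0.67 (0 to 0) of the lymphocyte list, and the rest as given. Of the members measured, the other hepatocyte libraries held 8 of 14 macrophage, 4 of 13 stellate, 3 of 14 endothelial, 2 of 9 neutrophil and 12 of 21 biliary genes at 1 RPKM or more, and no lymphocyte or platelet gene. A mislabelled ductal sample is argued against, since library 118 correlated better with the other hepatocytes (0.931) than with hepatocyte-derived (0.772) or cholangiocyte-derived ductal libraries (0.669), a margin of 0.159. The labels state the exclusion of CD11b, CD26, CD31 and CD45 for ductal cells and give no gate for hepatocytes, and no biological explanation was tested.

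Hepatocyte-derived ductal library 611 differed from its group in several values. Its scores were 2.90 for fetal liver genes (2.56 to 2.65 in the others), 6.09 for epithelial junctions (5.99 to 6.01) and 0.918 for platelet genes (0.674 to 0.742). It held Ctgf at 296 (167.8 to 200.9), Cxcl5 at 36.4 (12.8 to 19.1), Epcam at 136 (60.8 to 81.9), Pf4 at 5.04 (1.47 to 2.31), Prom1 at 43.6 (20 to 25.9) and Rgs4 at 58.7 (16.1 to 23.9). Sex-linked scores were 0.052, 0.056 and 0.076 in the hepatocyte-derived, cholangiocyte-derived and hepatocyte libraries with the number 611, against 4.29 to 4.42, 4.09 to 4.29 and 3.58 to 3.99 in the others. This list names Y-linked genes and Xist, and 4 of its 5 members were found in the table. Scores near 0 leave next to no transcripts of any member found, Y-linked genes among them. Female cells lack Y-linked transcripts but hold Xist, so reading these libraries as female requires that Xist is the member not found. Each group includes a library with this number, and sex was not part of the model. Whether sex bears on the other values of these libraries was not tested. Hepatocyte library 611 had 22% of its RPKM in the 10 most abundant genes (18.1 to 18.5%), Akr1d1 at 121 (55 to 58.6), Ass1 at 426 (284.5 to 301.4), Fah at 359 (258.5 to 273.7), Prom1 at 28.9 (1.33 to 3.32) and Slc6a13 at 166 (134.9 to 137.5). Cholangiocyte-derived library 611 held Igfbp7 at 857 (1150.3 to 1246) and Pcna at 37.8 (45.6 to 48.2).

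Both ductal libraries numbered 219 had a low macrophage score. It was 0.994 in hepatocyte-derived library 219 (3.01 to 3.42) and 1.43 in cholangiocyte-derived library 219 (3.79 to 4.52), and the former also had low endothelial (0.499 against 1.55 to 1.93) and neutrophil scores (0.067 against 1.28 to 1.57) and Ms4a4d at 129 (68.8 to 75.2). Cholangiocyte-derived library 219 held Rad51l1 at 21.9 (1.5 to 4.19) and Rgs5 at 844 (480.8 to 583). Hepatocyte-derived library 220 held Rgs5 at 953 (1453 to 1613) and Ttr at 971 (608 to 667.3). The primary cilium score of cholangiocyte-derived library 118 was 3.95 (4.13 to 4.18), and hepatocyte library 248 held Jag1 at 2.26 (1.08 to 1.19).

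Secreted protein genes were higher in hepatocyte-derived than in cholangiocyte-derived ductal libraries, with 16 called. Hepatocytes or their RNA carried into the sort would add the same share of every hepatocyte transcript, yet 26 abundant xenobiotic and bile acid genes allow a share of 0.885 to 4.44% by library, taken at the lower quartile of their ratio to hepatocytes, while the called members stood at medians of 19.3 to 26% of the hepatocyte level. The margin was 5.85-fold or more, lowest in library 220, which argues against carry-over as the whole source, while a part of that share remains open. The members were chosen as higher in these same libraries, and carried cells are assumed to match the sorted hepatocytes. In cholangiocyte-derived libraries the margin ran from 1.63-fold to 19.8-fold, so a large margin was not particular to hepatocyte-derived ones. After rescaling by median ratios 16 of 16 members were still called. That rescaling moved the median log2 fold change of all genes only from -0.029 to -0.006, so it hardly tested the scaling to library size. Under quantile normalization, which moved the gene counts more, 14 of the 20 list members were called higher and 0 lower. Most of the list thus stayed higher under each scaling used. Retention of a part of the secretory program after the change of cell type may be an explanation and was not tested.

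Cell cycle genes were lower in hepatocyte-derived than in cholangiocyte-derived ductal libraries, in all 22 members. With the macrophage and the stellate score of each library as covariates, 10 of 22 were called, and the median log2 fold change went from -1.31 to -0.81 while its median SE rose from 0.261 to 0.307, so calls ended both by a smaller change and by a wider error. Stromal and immune cells in the sort could therefore account for part of the pattern, though the scores are partly confounded with the groups, the gate excluded CD11b, CD31 and CD45, and library 219 of the cholangiocyte-derived group had a macrophage score of 1.43 with a cell cycle score of 3.58. The stellate score of that library was 2.92, above the 1.46 to 2.16 of hepatocyte-derived libraries, so it does not speak against stromal cells. After rescaling 21 of 22 were called lower, but that rescaling hardly moved this comparison, as given for the secreted proteins. Under quantile normalization 19 were called lower and 0 higher, so most members stayed lower under each scaling used. A difference in proliferation by origin, or between donor and host cells, stays open and was not tested.

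In each comparison 1 of 100 splits of the libraries, the real one, gave as many called genes. This argues against a random division of the libraries as the source of these numbers. A share of 1 in 100 is the smallest these splits can give, and they exchanged libraries without regard to the shared sample numbers. The real counts were 10236 for hepatocyte-derived ductal cells against hepatocytes, 10670 for cholangiocyte-derived ductal cells against hepatocytes and 4570 between the ductal groups. The highest other splits gave 9040, 9274 and 10. The splits with 9040 and 9274 exchanged 4 libraries and so again kept the 4 hepatocyte libraries together, which shows the structure of the samples.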

How the results depend on the processing

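Adding the transcripts of a symbol, a block from the numbers in the column names, exchanging score labels within numbers, leaving out 3 libraries and rescaling the lists were tests chosen only after the result was seen. Across the alternatives, 387 of 412 counts stayed within 1.5 times their value, and for genes and scores 5145 values kept direction and side of the threshold, 88 lost a call, 32 gained one and 6 reversed, while for lists 1686 kept theirs, 59 lost a call and 40 gained one. Of 571 ratios and similarity values, 558 moved by less than the spread, and each ratio that moved further did so without hepatocyte library 118 and was then larger. For a ratio the spread is the SDs of both groups carried into it. Ratios of scattered genes, such as Rad51l1 and Col1a1, could therefore move widely without other libraries and stay within it. The scalings moved gene counts. For hepatocyte-derived ductal cells against hepatocytes, 8363 higher and 1873 lower became 4842 and 4486 after rescaling by median ratios and 4596 and 4136 under quantile normalization. For cholangiocyte-derived ductal cells 8475 and 2195 became 5257 and 4688, and 4891 and 4769. Between the ductal groups 1913 higher became 3069 under quantile normalization and 2987 with library weights. The scalings centre the median of all genes near 0 by construction, and for the weights the cause was not tested. At least 2-fold changes were 1951 and 1975, and 2680 and 2263, after rescaling, 1569 and 1462, and 2170 and 1996, under quantile normalization, and with a pseudocount of 5, which shrinks low genes, 2096 and 2856 higher in the 2 comparisons with hepatocytes and 294 higher and 440 lower between the ductal groups. An estimated correlation left 10, 10 and 0 of 17, 16 and 12 list calls. The similarity difference of 0.106 was 0.143 with a stricter filter, and the cause was not tested.

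Reversed values were Cd14 in hepatocyte-derived ductal cells against hepatocytes (-0.66 after rescaling) and, with the median in place of the mean of members, scores for hepatocyte transcription factors (0.005) and Wnt targets (-0.70) in the same comparison, Wnt targets in cholangiocyte-derived ductal cells against hepatocytes (-0.63), and fetal liver (0.38) and platelet genes (0.057) between the ductal groups. The cell cycle score of the first comparison passed the threshold with the median (-0.68, exact permutation p = 0.0317). The cause was not tested. Without 1 library, the cell cycle score of cholangiocyte-derived ductal cells against hepatocytes was 0.82 to 1.12, and with fewer samples it no longer passed in 7 cases (exact permutation p of 0.0536 to 0.0571). Over the 29 alternatives, adjusted p ranged from 0.0102 to 0.838 for Alb between the ductal groups (11 calls lost), from 7.06e-06 to 0.479 for Pf4 (9 lost) and 9.18e-07 to 0.0523 for Hnf4a (1 lost) in hepatocyte-derived ductal cells against hepatocytes, and for cholangiocyte-derived ductal cells against hepatocytes from 2.98e-05 to 0.185 for Vim (4 lost), 0.00108 to 0.712 for Clec4g (4 gained) and 1.79e-04 to 0.388 for S100a9 (5 gained). Between the ductal groups it was 0.00458 to 0.878 for Cd24a (4 gained). Counts without 1 library were 8152 to 8682 higher and 1750 to 1884 lower, 8260 to 8789 and 2061 to 2196, and 1603 to 2385 and 2299 to 3296 in the 3 comparisons.

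With the sample number as a block, whose correlation was 0.233, counts were 8278 and 1897, 8386 and 2190, and 1562 and 2227. Hepatocyte-derived ductal cells and hepatocytes were not taken as paired, since not every correlation met the criterion (0.021 to 0.193, against a median of -0.059 for other pairs). This cannot show that they are unpaired, since numbers 225 and 611 occur in all 3 groups and were taken to pair the other combinations. Sex-linked scores also set the libraries numbered 611 apart in all groups, and 9 of 12 libraries correlated best with their own number. Between hepatocyte-derived ductal cells and hepatocytes the block gave calls of higher levels for Clec4g (adjusted p = 0.0358), S100a9 (2.65e-04), Notch (0.0499) and immediate early genes (0.0318), and none for endothelial (0.817) and macrophage markers (0.493). Within all 3 shared numbers hepatocyte-derived ductal cells had the higher macrophage (by 1.26 to 1.62), endothelial (0.683 to 1.47), stellate (1.06 to 1.08) and neutrophil scores (0.943 to 1.24), although over all libraries no exchange test passed for these (exact permutation p of 0.333 to 1). With score labels exchanged within numbers, the cell cycle score of cholangiocyte-derived ductal cells against hepatocytes (0.94) and the chemokine score of hepatocyte-derived ones (1.47) no longer passed before adjustment (exact permutation p = 0.0833 for each), nor did the platelet score between the ductal groups (0.0833), where macrophage, endothelial, lymphocyte, pericentral and immediate early scores did (0.0417, the smallest possible). These exchanges left the ductal libraries numbered 220 unpaired. With them paired too, no score between the ductal groups could reach 0.05. After adjustment no score passed in any comparison (lowest adjusted p of 0.059, 0.0506 and 0.0545). Beyond these and the blocked values in the report it changed no other call of a gene, list or score given here, while the counts moved as stated. Low values are limited by depth and by the rounding to 2 decimals.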

Other observations

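The genes named here were chosen after their values were seen. Prox1, Onecut2 and Hes1, genes of transcription factors, were higher in both ductal groups than in hepatocytes. Prox1, a homeobox factor of early liver development, was at 65.5 ± 8.39 RPKM in hepatocyte-derived and 66.6 ± 24.2 in cholangiocyte-derived ductal cells against 21.6 ± 6.01 in hepatocytes (limma log2 fold changes of 1.59 and 1.55), and Onecut2 at 37.7 ± 7.4 and 47.2 ± 11.4 against 10.5 ± 4.58. Hes1, a transcriptional target of Notch, was at 219 ± 67.6, 738 ± 282 and 35.3 ± 21.8, with log2 fold changes of 2.78 and 4.49 against hepatocytes.

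Called mucin and secretory genes went in both directions, while the score of the list was 2.10 in cholangiocyte-derived ductal cells against 1.38 in hepatocytes and 1.38 in hepatocyte-derived ductal cells (exact permutation test, adjusted p = 0.0104 and 0.0208). Tff2, a trefoil peptide of mucous epithelia, was at 12.2 ± 7.32 RPKM in hepatocyte-derived and 98 ± 12.2 in cholangiocyte-derived ductal cells against 0.44 ± 0.662 in hepatocytes. Dmbt1 was at 3.18 ± 1.29 in cholangiocyte-derived ductal cells and at 0.014 ± 0.0134 and 0.0125 ± 0.025 in hepatocyte-derived ductal cells and hepatocytes. Pigr, which carries immunoglobulin A across epithelia, was highest of the 3 groups in hepatocytes, at 535 ± 129.4 against 58.5 ± 14.7 and 32.1 ± 11.2. Col1a2 was at 32.7 ± 35.9 in cholangiocyte-derived ductal cells, 0.87 ± 1.01 in hepatocyte-derived ductal cells and 2.30 ± 4.18 in hepatocytes.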
